A study of Homo sapiens with 42 samples.

How the data were processed

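The series holds RNA sequencing of WTC11, a human induced pluripotent stem cell line of wild-type genotype, at day 0 and along an atrial and a ventricular cardiomyocyte differentiation. Per the labels' protocols, cells grew in 1 well per replicate, were trypsinized and snap frozen, and total RNA was isolated with a column kit. The protocols name Illumina Stranded Total RNA Prep and Ribo-Zero Plus and equal RNA mass for every library. This kit aims to keep the strand, remove ribosomal RNA and read RNA without a poly(A) tail, such as histone and non-coding RNA. Yet mitochondrial ribosomal RNA took 39.0% of counts in the ventricular and day 0 libraries.

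The authors deposited a table of estimated counts per gene and a table of TPM, each with 29744 genes and a column for each of the 42 libraries. Per the submitters' processing notes, STAR, Salmon and the human genome build hg38 were used. Their roles, versions, annotation and strand setting are not given in the sources used here, nor whether all libraries were prepared and processed together. The deposited estimated counts are not normalized, and 19.8% of the values in a library were not whole on average (17.1 to 21.9%), so they were rounded to whole numbers before testing. The deposited TPM are the authors' values, transcripts-per-million values scaled for gene length over all genes, structural RNAs included. Small structural RNAs took 68.8% of the deposited TPM in the atrial libraries (mean of 18) and 1.60% in the ventricular and day 0 libraries (mean of 24), so that TPM of other genes are not comparable between the 2 library sets. Mitochondrial ribosomal RNA took 36.2% of TPM on ventricular day 2, 51.3% on day 10 and 68.5% on day 30. TPM of other genes are therefore not comparable over the ventricular days either. Columns of other samples numbered 0.

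Each column was matched to a sample by its name, and each sample to 1 of 14 groups by the course, day and replicate in its title. The library names of all 3 day 0 replicates carry a ventricular tag, and the treatment label of replicate 3 names the atrial differentiation, but their titles name no course. The labels do not say if wells of a group were separate differentiations. P-values use the spread between wells, which is pooled over all groups and may be technical in part. No pair of replicates agreed within sampling noise (lowest chi-square per degree of freedom 5.57), so all 42 were kept. Depth ranged from 17633742 to 41021323 estimated counts per library, of which mitochondrial ribosomal RNA took up to 57.6%. A gene with 0 counts over a group was given a floor of 3 counts over that group.

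Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 19992, libraries were scaled by TMM, and 1 robust quasi-likelihood model without intercept was fitted to the 14 groups, with 28 residual degrees of freedom. Each of 17 comparisons was a contrast in that model, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05 and a log2 fold change above 1 in size. Adjusted p-values of genes come from edgeR's quasi-likelihood test. All adjusted p-values for a list come from camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and were repeated with an estimated correlation. Called members of a list were also counted with adjustment over the list alone, which changed the counts in 102 of 480 pairs of list and comparison, by at most 5 genes.

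The designs, the alternatives, the 24 gene lists and the rule for naming genes were fixed before the data were examined. The rule named 17 core genes in every group. For each atrial to ventricular comparison it took the 8 genes with the largest log2 fold change in each direction, and for other comparisons the 4 largest. These had to be called, to reach a mean of at least 5 TPM in the higher group, to have no overlap between the libraries compared and to have an approved-style symbol. From each list it took up to 4 called members with the largest change and the best expressed member not called. The text gives only part of the genes the rule names, chosen after their values were seen for a known function, and a gene with at most 3 counts over 1 group is given by its levels or a lower bound in place of a fold change. For 34 named values a compared group held more than 3 and at most 15 counts over its libraries, and the size of such a fold change is uncertain. The skeletal muscle list had 4 of 6 members tested, under the minimum of 5 for a list test, and on day 4 it had 0 members higher and 3 lower in the atrial libraries.

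Positions, lengths and overlaps came from GENCODE release 29 (GRCh38), which held 22618 of the deposited symbols (76.0%). The tables hold 61 repeated symbols with a number added, which are treated as separate genes. Since the strand setting of the counting is not given, genes that overlap a gene on the other strand are uncertain. So are near-identical copies such as histone genes, metallothioneins and BOLA2B.

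The model was tested on simulated counts with 200 changed genes among 19992. Recovery was counted at an adjusted p below 0.05 alone, without the fold threshold. In the simulated atrial to ventricular comparison of day 6 it recovered 95% of genes changed 4-fold and 77% of those changed 2-fold. Of the genes that passed, 4.97% were false. In the simulated ventricular step from day 4 to day 6 it recovered 95% and 80%, with 1.69% false. With the fold threshold, 95% of genes changed 4-fold were called in each, with 7 and 1 false calls. Simulated means were pooled over all libraries and few genes changed. These rates do not cover differing library sets or groups of unequal spread.

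A few genes that the rule names are not reported here. Alternatives were RLE scaling, no filter (28236 genes), DESeq2 1.42.0, a fit of only the compared groups, the replicate number as a block, no fold threshold, limma on log2(TPM + 1) and on log2(TPM + 0.1), removal of 552 structural RNA and histone genes, other days for the early and last stages, and each library left out in turn. Values relative to day 2, and the removal of genes that overlap an exon on the opposite strand or are not in the annotation, were added after the data were seen. XIST and Y-linked genes were left out of all named genes. Chance was assessed with other splits of the same libraries.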

Results

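Gene expression was measured by RNA sequencing in WTC11, a human induced pluripotent stem cell line, before differentiation (day 0) and along an atrial and a ventricular cardiomyocyte differentiation. The atrial course was sampled on days 2, 4, 6, 11, 20 and 45 and the ventricular course on days 2, 4, 6, 10, 12, 15 and 30. The labels call the cells of days 2 and 4 cardiac mesoderm, those of day 6 cardiac precursors and later ones cardiomyocytes. Each of the 14 groups held 3 biological replicates, grown in 1 well each, so that 42 libraries were compared. Estimated counts per library summed to between 17633742 and 41021323 (mean 26423000 in the 18 atrial libraries and 34513000 in the 24 ventricular and day 0 libraries). Of 29744 genes, 19992 had enough counts to be tested. A gene was called when its adjusted p was below 0.05 and its log2 fold change exceeded 1 in size. Levels are TMM-scaled counts-per-million values (CPM), mean ± SD over 3 libraries. Each bracketed value after a gene is its log2 fold change, and a ± after a log2 fold change is its standard error (SE). Where limma's test on log2(TPM + 1) or log2(TPM + 0.1) moved the share of higher calls by over 10 percentage points, its numbers follow those of the main test.

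The libraries fell into 2 sets that differed in composition. The first principal component (35.9% of variance) followed time. The second (28.1%) parted all 18 atrial libraries from all ventricular and day 0 libraries. Mitochondrial ribosomal RNA took 0.19% of counts in the atrial libraries (range 0.066 to 0.50%) and 39.0% in the ventricular and day 0 libraries (24.2 to 57.6%). Small structural RNAs took 5.33% (4.18 to 8.20%) and 0.030% (0.013 to 0.052%). A direct atrial to ventricular comparison, and atrial day 2 against day 0, therefore hold the library set together with the biology, and the course and the library set cannot be told apart there. Steps within a course, and differences between the courses' steps, cancel any offset of a gene that stays the same over time. Exons of 24 genes whose values are given overlap those of a gene on the opposite strand, and with the strand setting of the counting not given their values are uncertain, above all between the library sets. These are A2M, ACTA2, ALDH1A2, BHLHE40, DKK1, ENO1, HAND2, HOXA3, HOXB2, HOXB3, IGF2, MCM2, MGP, NPPA, NR2F1, PAX6, POU5F1, RARB, SHOX2, SLC2A1, SLC8A1, TBX1, TBX5 and TDGF1. A change of the overlapping gene over time does not cancel in a difference of steps.

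**Figure D1:**
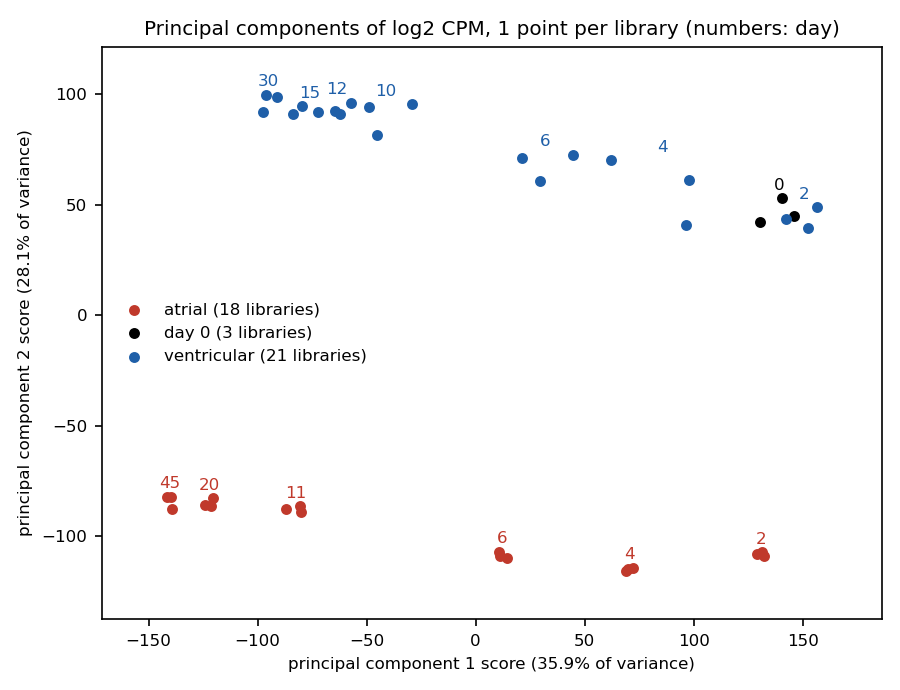
Principal components 1 and 2 of log2 CPM (each axis in component score, with its share of variance) for the 42 libraries, 1 point per library, coloured by course and marked with the day. Component 2 lies between -116 and -82 in the atrial libraries and between 39 and 100 in the ventricular and day 0 libraries.

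The series title names a heart disease-linked transcription factor. TBX5, a T-box factor needed for heart formation and mutated in Holt-Oram syndrome, is described first (chromosome 12, 114353931 to 114408442, minus strand, GRCh38, protein-coding). Its exons overlap TBX5-AS1 on the opposite strand, so that its values are uncertain between the library sets. It was close to absent at day 0 (0.169 ± 0.0905 CPM) and on day 2 of the atrial (0.0801 ± 0.0578, from 1, 3 and 4.62 counts) and ventricular course (0.430 ± 0.370). In the atrial course it stood at 46.8 ± 2.39 CPM on day 4, 59.6 ± 11.5 on day 6, 103 ± 15 on day 11, 105 ± 24.4 on day 20 and 139 ± 29.3 on day 45. In the ventricular course it stood at 3.26 ± 2.17 CPM on day 4, 31.3 ± 25.3 on day 6, 36.8 ± 17 on day 10, 69.1 ± 24.3 on day 12, 85.5 ± 10 on day 15 and 93.1 ± 48.4 on day 30. The deposited TPM, which are not comparable between the library sets or over the ventricular days, were 0.0627 ± 0.0358 at day 0. Along the atrial days they were 0.0218 ± 0.0160, 14.9 ± 0.754, 19.5 ± 3.58, 30.4 ± 5.74, 37.0 ± 8.78 and 41.8 ± 7.70. Along the ventricular days they were 0.127 ± 0.10, 1.25 ± 0.761, 13.4 ± 10, 14.9 ± 7.41, 23.7 ± 7.07, 24.2 ± 1.48 and 21.4 ± 11.7. TBX5 rose from day 2 to day 4 in both courses, by a log2 fold change of 9.16 ± 0.770 in the atrial and 2.94 ± 0.651 in the ventricular course (not called with log2(TPM + 1), 0.94), and the atrial rise was larger by 6.22 ± 1.20 (adjusted p = 0.000504). Over days 2 to 6 the difference of the rises was 3.32 ± 1.20 and missed the threshold (adjusted p = 0.0634). TBX5 was higher in the atrial libraries on day 4 (3.83 ± 0.509, adjusted p = 1.47e-07) and day 11 against days 10 and 12 (1.04 ± 0.368, adjusted p = 0.0154). It was not called on day 6 (0.93 ± 0.444, adjusted p = 0.0709) or between the last days (0.58 ± 0.439, adjusted p = 0.255). Without ventricular day 6 replicate 2 the day 6 difference was called (1.80), as was the difference of the rises to day 6 (4.19, and 3.81 without ventricular day 2 replicate 2). With the replicate number as a block both were called (1.07 and 3.49), as was the difference of the rises with DESeq2 (3.40) and that of the last days with log2(TPM + 1) (1.06) and log2(TPM + 0.1) (1.10). The day 11 difference stood at the fold threshold and lost its call without atrial day 11 replicate 1 (0.92), without replicate 1 or 3 of ventricular day 10 (0.99 and 0.91) and without replicate 1 or 3 of ventricular day 12 (0.96 and 0.98). It also lost it with RLE scaling (0.98), DESeq2 (0.98), log2(TPM + 1) (0.72), log2(TPM + 0.1) (0.76) and ventricular day 12 alone (0.58).

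**Figure D2:**
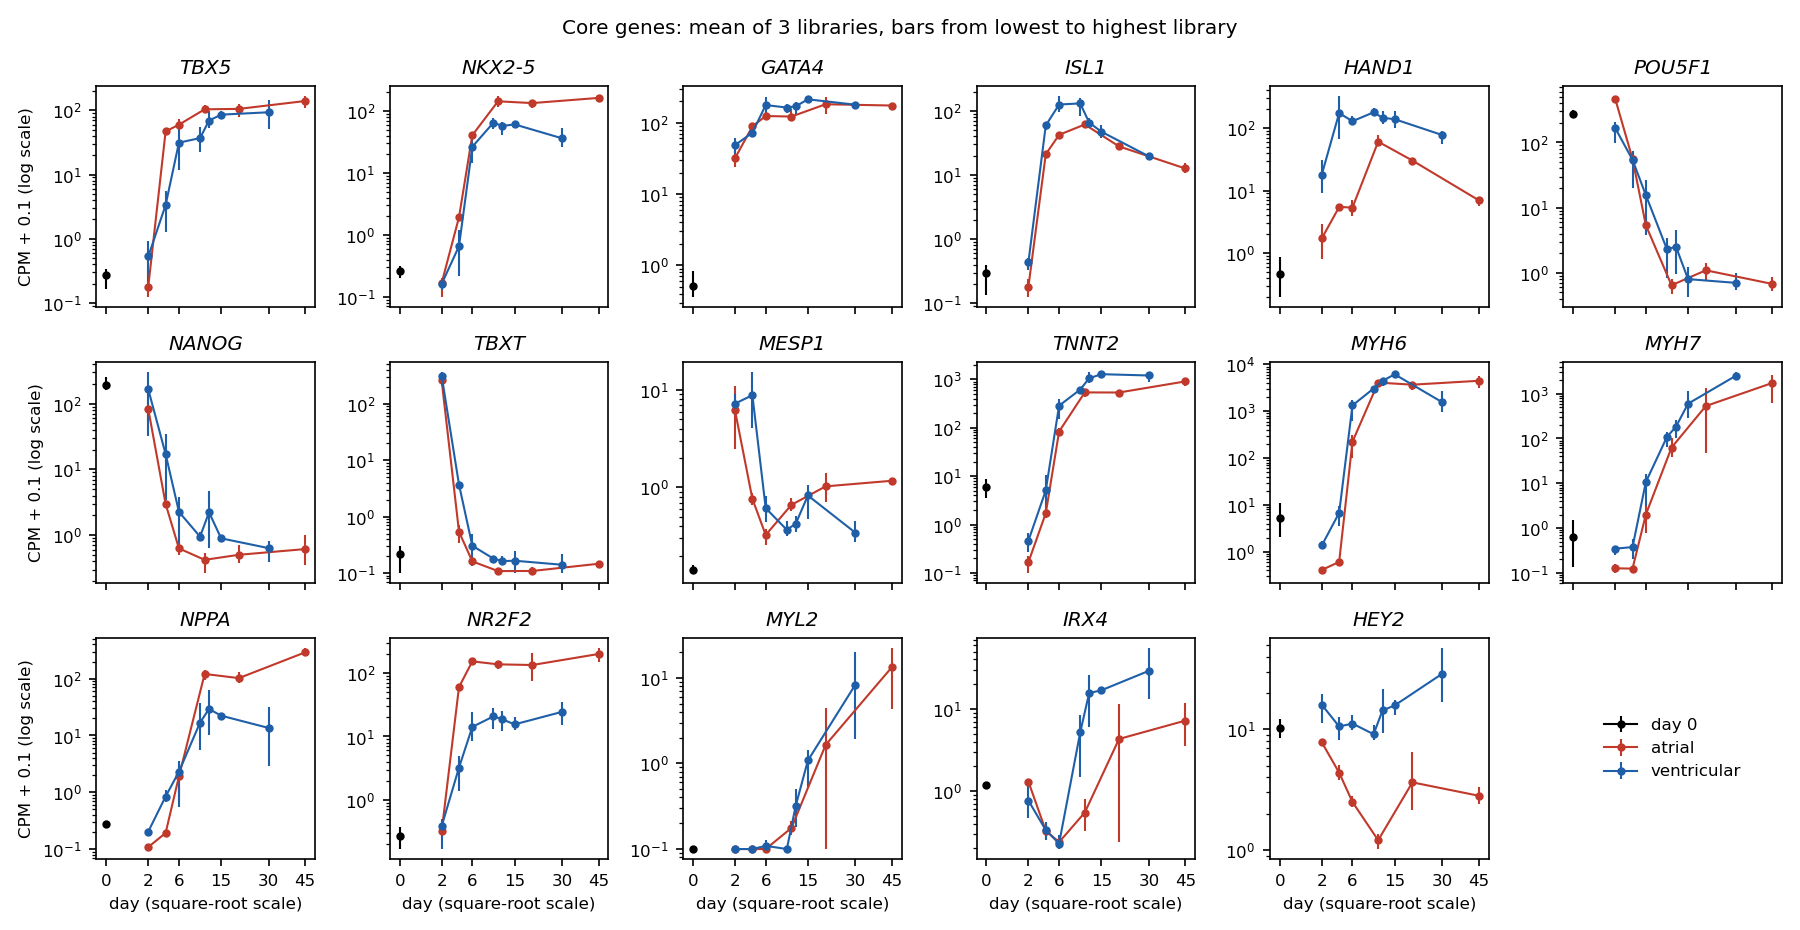
Levels of the 17 core genes over days of differentiation (x axis, days, square-root scale; y axis, CPM + 0.1 on a log scale). Points are the mean of 3 libraries, bars reach from the lowest to the highest library, and black, red and blue mark day 0, the atrial and the ventricular course. TBX5 reached 46.8 CPM on atrial day 4 and 3.26 CPM on ventricular day 4.

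Levels of other core genes are given by day, without a test of their order. POU5F1, a pluripotency factor, stood at 271 ± 36.9 CPM at day 0, 470 ± 64.5 and 167 ± 59.4 on atrial and ventricular day 2, and 0.578 ± 0.166 and 0.603 ± 0.253 on the last days. NANOG went from 194 ± 50.6 CPM at day 0 to 2.88 ± 0.373 and 17 ± 15.5 on day 4. TBXT, the primitive streak T-box factor, was near absent at day 0 (0.118 ± 0.105) and stood at 261 ± 49.2 CPM on atrial and 314 ± 43.7 on ventricular day 2. MESP1, an early cardiac mesoderm factor, stood at 6.06 ± 4.41 and 7.14 ± 1.80 CPM on day 2. GATA4 stood at 31.6 ± 8.62 and 48.4 ± 12.5 CPM on day 2 and at 124 ± 19.5 and 176 ± 50.2 on day 6. NKX2-5 reached 40.6 ± 3.61 and 26.4 ± 14.3 CPM on day 6. The second heart field factor ISL1 was highest on atrial day 11 (61.5 ± 4.31) and ventricular day 10 (131 ± 41.3). Cardiac troponin T, TNNT2, stood at 905 ± 168 CPM on atrial day 45 and 1201 ± 274 on ventricular day 30. MYL2, the ventricular myosin light chain, stood at 13.2 ± 8.90 and 8.23 ± 9.92 CPM on these days.

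The first question was what changed from day 0 to day 2. Genes of the primitive streak rose together in both courses. Of 17 primitive streak and mesendoderm genes tested, 17 rose and 0 fell in the atrial course, and 17 rose and 0 fell in the ventricular course, with adjusted p = 5.45e-14 and 5.12e-24 for the list and adjusted p = 0.000103 and 9.26e-07 with an estimated correlation. The T-box factor TBXT rose by 11.33 ± 0.394 and 11.07 ± 0.392 (ventricular and atrial), from 6, 0 and 5 counts at day 0. The mesoderm factor MSGN1 had 0 counts at day 0 and was at least 826-fold higher on ventricular day 2, against a floor of 3 counts over the group. Of 10 WNT targets tested, 9 rose and 0 fell in the atrial course, and 9 rose and 0 fell in the ventricular course, with adjusted p = 2.23e-07 and 9.59e-15 for the list and adjusted p = 0.00310 and 2.28e-05 with an estimated correlation. DKK4, a secreted WNT antagonist, rose by 12.36 and 11.90 (ventricular and atrial). Of 12 cardiac mesoderm genes tested, 6 rose and 0 fell in the atrial course, and 9 rose and 0 fell (9 and 1 adjusted over the list alone) in the ventricular course, with adjusted p = 0.0358 and 1.3e-06 for the list and adjusted p = 0.807 and 0.0391 with an estimated correlation. The apelin receptor APLNR (10.24), the stem cell receptor LGR5 (9.72) and MESP1 (7.25) rose. Of 12 pluripotency genes tested, 0 rose and 7 fell in the atrial course, and 0 rose and 7 fell in the ventricular course, with adjusted p = 0.112 and 0.00888 for the list and adjusted p = 0.807 and 0.486 with an estimated correlation. UTF1 (-3.68), PRDM14 (-2.42) and SOX2 (-2.32) fell. SOX2 lost its call without ventricular day 2 replicate 2 (-1.80), ventricular day 2 replicate 3 (-2.47) or day 0 replicate 1 (-2.20), and with only the compared groups fitted (-2.33). Of 20 retinoic acid response genes tested, 16 rose and 1 fell in the ventricular course, with an adjusted p = 6.6e-08 for the list and an adjusted p = 0.0594 with an estimated correlation. HOXB1 (8.85), a HOX gene near the 3' end of its cluster, was among them. Of 14 glycolysis genes tested, 10 rose and 0 fell in the ventricular course, with an adjusted p = 1.43e-07 for the list and an adjusted p = 0.178 with an estimated correlation. By size, IDO1 (-7.50), a tryptophan-degrading enzyme, and SORBS2 (-6.93) were among the largest falls in the ventricular course. In the atrial course FGF17 (12.08) was among the largest rises. Called genes numbered 1973 higher and 2178 lower in the ventricular course (1333 and 2568 with log2(TPM + 0.1)) and 4239 and 3712 in the atrial course (1591 and 3247 with log2(TPM + 1), 2689 and 5121 with log2(TPM + 0.1)), where the library set changed together with the day.

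From day 2 to day 4 the primitive streak genes fell and cardiac transcription factors rose. Among the 17 primitive streak and mesendoderm genes, 0 rose and 17 fell in the atrial course, and 1 rose and 14 fell (1 and 15 adjusted over the list alone) in the ventricular course, with adjusted p = 1.84e-23 and 4.99e-13 for the list and adjusted p = 1.16e-06 and 0.000177 with an estimated correlation. TBXT fell in the atrial (-9.19) and the ventricular course (-6.45), as did the WNT antagonist DKK1 (-9.31 and -7.38). Of 20 cardiac transcription factors tested, 16 rose and 0 fell (16 and 1 adjusted over the list alone) in the atrial course, and 14 rose and 0 fell (15 and 1 adjusted over the list alone) in the ventricular course, with adjusted p = 1.16e-17 and 1.73e-10 for the list and adjusted p = 0.000761 and 0.0112 with an estimated correlation. The nuclear receptors NR2F1 (10.26) and NR2F2 (8.11), HAND2 (9.89) and TBX2 (9.87) were among those that rose, beside TBX5. ISL1 (7.47) and the serum response factor partner MYOCD (7.08) led in the ventricular course. Among the 20 retinoic acid response genes, 17 rose and 1 fell in the atrial course, and 4 rose and 5 fell in the ventricular course, with adjusted p = 7.3e-11 and 0.459 for the list and adjusted p = 0.0113 and 0.756 with an estimated correlation. The retinoic acid receptor RARB (9.39) and HOXB2 (7.60) rose in the atrial course. Of 10 posterior second heart field genes tested, 8 rose and 0 fell in the atrial course, with an adjusted p = 2e-08 for the list and an adjusted p = 0.00749 with an estimated correlation. The zinc finger factor OSR1 (7.91) rose in the atrial course, and the secreted factor WNT2 went from 0.00934 ± 0.0162 to 7.56 ± 2.45 CPM. Of 10 anterior second heart field genes tested, 9 rose and 1 fell in the atrial course, and 7 rose and 0 fell (7 and 1 adjusted over the list alone) in the ventricular course, with adjusted p = 1.1e-06 and 0.000481 for the list and adjusted p = 0.000761 and 0.0116 with an estimated correlation. Of 22 sarcomere genes tested, 8 rose and 1 fell in the atrial course, and 13 rose and 0 fell in the ventricular course, with adjusted p = 0.00178 and 4.77e-07 for the list and adjusted p = 0.382 and 0.170 with an estimated correlation. The light chain MYL4 (7.30) and the slow skeletal troponin TNNI1 (5.88) led. Of 10 endoderm markers tested, 7 rose and 1 fell in the atrial course, and 5 rose and 0 fell in the ventricular course, with adjusted p = 0.000239 and 0.0722 for the list and adjusted p = 0.217 and 0.537 with an estimated correlation. On atrial day 2 and day 4, transthyretin TTR stood at 0.00934 ± 0.0162 and 19.7 ± 5.83 CPM and alpha-fetoprotein AFP at 0.0167 ± 0.0290 and 7.54 ± 3.28 CPM. Among the 10 WNT targets, 1 rose and 7 fell in the atrial course, and 0 rose and 8 fell in the ventricular course, with adjusted p = 8.04e-07 and 5.44e-09 for the list and adjusted p = 0.00362 and 0.00103 with an estimated correlation. Of 10 epicardium markers tested, 5 rose and 0 fell in the atrial course, with an adjusted p = 0.00298 for the list and an adjusted p = 0.147 with an estimated correlation. Among the 14 glycolysis genes, 0 rose and 8 fell in the atrial course, with an adjusted p = 7.71e-07 for the list and an adjusted p = 0.147 with an estimated correlation. By size, the fibroblast growth factor FGF4 fell by 9.83 on the log2 scale in the atrial course. The natriuretic peptide NPPB had 0 counts on ventricular day 2 and was at least 244-fold higher on day 4. Called genes numbered 1768 higher and 2135 lower in the atrial (929 and 737 with log2(TPM + 1)) and 2281 and 1581 in the ventricular course (1208 and 517 with log2(TPM + 1), 2974 and 967 with log2(TPM + 0.1)). With only the compared groups fitted the ventricular numbers were 1456 and 1016.

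From day 4 to day 6, sarcomere genes rose in both courses. Among the 22 sarcomere genes, 18 rose and 0 fell in the atrial course, and 18 rose and 0 fell (19 and 0 adjusted over the list alone) in the ventricular course, with adjusted p = 2.1e-34 and 3.97e-35 for the list and adjusted p = 0.00117 and 0.000552 with an estimated correlation. The myosin heavy chain MYH6 rose by 8.78 ± 0.671 and 7.64 ± 0.608, and the myosin-binding protein MYBPC3 by 6.99 ± 0.692 and 6.69 ± 0.757 (atrial and ventricular). Of 14 calcium handling and ion channel genes tested, 10 rose and 1 fell in the atrial course, and 8 rose and 2 fell (8 and 3 adjusted over the list alone) in the ventricular course, with adjusted p = 2.76e-12 and 5.62e-07 for the list and adjusted p = 0.00154 and 0.0164 with an estimated correlation. The phospholamban gene PLN (5.42) and the sodium-calcium exchanger SLC8A1 (3.44) rose in the atrial course. Among the 20 cardiac transcription factors, 7 rose and 1 fell (8 and 1 adjusted over the list alone) in the atrial course, and 13 rose and 0 fell (14 and 2 adjusted over the list alone) in the ventricular course, with adjusted p = 1.18e-07 and 5.07e-12 for the list and adjusted p = 0.0228 and 0.00564 with an estimated correlation. NKX2-5 rose by 4.47 and 5.56 and the muscle methyltransferase SMYD1 by 7.25 and 5.89 (atrial and ventricular). Of 7 smooth muscle markers tested, 6 rose and 0 fell in the atrial course, and 4 rose and 0 fell (5 and 1 adjusted over the list alone) in the ventricular course, with adjusted p = 1.46e-10 and 1.82e-05 for the list and adjusted p = 0.00357 and 0.0475 with an estimated correlation. The smooth muscle actin ACTA2 rose by 4.70 and 4.17 (atrial and ventricular). Of 10 sinoatrial and pacemaker genes tested, 4 rose and 0 fell (6 and 0 adjusted over the list alone) in the atrial course, and 4 rose and 0 fell (5 and 0 adjusted over the list alone) in the ventricular course, with adjusted p = 5.18e-05 and 0.0125 for the list and adjusted p = 0.0140 and 0.125 with an estimated correlation. The pacemaker channel HCN4 rose by 3.39 in the atrial course. Of 10 endothelium markers tested, 4 rose and 1 fell (7 and 1 adjusted over the list alone) in the atrial course, and 8 rose and 1 fell in the ventricular course, with adjusted p = 0.00373 and 6.6e-06 for the list and adjusted p = 0.20 and 0.0481 with an estimated correlation. The junction gene CDH5 rose by 6.02 and PECAM1 by 3.22 in the ventricular course, PECAM1 by 2.08 without ventricular day 6 replicate 3. PECAM1 lost this call with log2(TPM + 1) (0.93) and with only the compared groups fitted (3.23). For the 17 primitive streak and mesendoderm genes, 0 rose and 11 fell (0 and 14 adjusted over the list alone) in the ventricular course, with an adjusted p = 2.23e-11 for the list and an adjusted p = 0.000552 with an estimated correlation. Among the 12 pluripotency genes, 0 rose and 6 fell in the atrial course, with an adjusted p = 4.67e-07 for the list and an adjusted p = 0.0638 with an estimated correlation. The co-receptor gene TDGF1 fell by 4.35 on the log2 scale. By size, the ventricular course also had falls of FGF17 (-6.40) and LEFTY2 (-6.09). Called genes numbered 851 higher and 449 lower in the atrial and 975 and 526 in the ventricular course. With only the compared groups fitted they were 1296 and 651 and 429 and 151, so that the order of the courses turned.

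From day 6 to the early cardiomyocytes, atrial day 11 and ventricular day 10, contractile and metabolic genes rose. For the 22 sarcomere genes, 20 rose and 0 fell in the atrial course, and 16 rose and 0 fell in the ventricular course, with adjusted p = 7.14e-19 and 3.66e-08 for the list and adjusted p = 0.0132 and 0.214 with an estimated correlation. MYL3 rose by 7.66 and 4.11 and the heavy chain MYH7 by 5.04 and 3.36 (atrial and ventricular). Of 20 fatty acid oxidation and oxidative metabolism genes tested, 12 rose and 0 fell (12 and 1 adjusted over the list alone) in the atrial course, and 9 rose and 0 fell in the ventricular course, with adjusted p = 2.88e-09 and 1.45e-07 for the list and adjusted p = 0.0168 and 0.0785 with an estimated correlation. Creatine kinase CKM rose by 8.60 and 4.88, and the fatty acid binding protein FABP3 by 4.53 and 2.78. For the 14 glycolysis genes, 13 rose and 0 fell in the atrial course, and 8 rose and 0 fell in the ventricular course, with adjusted p = 2.03e-12 and 3.66e-08 for the list and adjusted p = 0.0472 and 0.214 with an estimated correlation. The glucose transporter SLC2A1 rose by 3.55 and 2.77. Among the 14 calcium handling and ion channel genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone) in the atrial course, and 11 rose and 0 fell in the ventricular course, with adjusted p = 2.78e-10 and 3.02e-08 for the list and adjusted p = 0.0132 and 0.0328 with an estimated correlation. Of 14 cell cycle genes tested, 0 rose and 2 fell in the atrial course, and 0 rose and 12 fell in the ventricular course, with adjusted p = 0.00805 and 1.58e-07 for the list and adjusted p = 0.437 and 0.238 with an estimated correlation. RRM2 (-2.53) and MCM2 (-2.04), genes of DNA replication, fell in the ventricular course. Of 16 atrial markers tested, 10 rose and 1 fell in the atrial course, with an adjusted p = 2.45e-06 for the list and an adjusted p = 0.0132 with an estimated correlation. The natriuretic peptide NPPA (6.07), the connexin GJA5 (5.09) and sarcolipin SLN (4.72) rose. Of 11 ventricular markers tested, 6 rose and 0 fell in the ventricular course, with an adjusted p = 0.00450 for the list and an adjusted p = 0.324 with an estimated correlation. The Iroquois factor IRX4 (5.21) and PLN (2.11) rose, and PLN lost its call without ventricular day 10 replicate 2 (1.30) and with only the compared groups fitted (2.13). For the 20 retinoic acid response genes, 1 rose and 10 fell in the atrial course, with an adjusted p = 0.00509 for the list and an adjusted p = 0.318 with an estimated correlation. The retinoic acid hydroxylase CYP26A1 (-7.81) and HOXB1 (-4.57) fell. Among the 10 endoderm markers, 0 rose and 7 fell (1 and 7 adjusted over the list alone) in the atrial course, with an adjusted p = 0.0151 for the list and an adjusted p = 0.396 with an estimated correlation. Among the largest changes were rises of HHATL (6.67) and BHLHE40 (5.55) in the ventricular and of A2M (8.54) in the atrial course. Called genes numbered 2218 higher and 1593 lower in the atrial (780 and 988 with log2(TPM + 1), 1457 and 2021 with log2(TPM + 0.1)) and 1633 and 1301 in the ventricular course (562 and 866 with log2(TPM + 1), 1203 and 1573 with log2(TPM + 0.1)).

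From the early to the last cardiomyocytes, atrial day 45 and ventricular day 30, matrix and fibroblast genes rose in both courses and endoderm markers fell. Of 12 fibroblast and extracellular matrix markers tested, 9 rose and 0 fell in the atrial course, and 10 rose and 0 fell in the ventricular course, with adjusted p = 0.000349 and 1.35e-05 for the list and adjusted p = 0.278 and 0.228 with an estimated correlation. Decorin, DCN, rose by 4.55 and 6.82 and fibrillin FBN1 by 4.31 and 3.76 (atrial and ventricular). For the 10 endoderm markers, 0 rose and 9 fell (1 and 9 adjusted over the list alone) in the atrial course, and 1 rose and 8 fell in the ventricular course, with adjusted p = 1.93e-05 and 0.000323 for the list and adjusted p = 0.278 and 0.288 with an estimated correlation. The pioneer factor FOXA2 fell by 6.85 on the log2 scale in the ventricular course. Among the 7 smooth muscle markers, 5 rose and 0 fell in the atrial course, and 5 rose and 0 fell in the ventricular course, with adjusted p = 0.00777 and 0.0144 for the list and adjusted p = 0.288 and 0.288 with an estimated correlation. Of 22 sarcomere genes tested, 7 rose and 0 fell in the atrial course, and 8 rose and 0 fell in the ventricular course, with adjusted p = 0.00119 and 0.0142 for the list and adjusted p = 0.366 and 0.442 with an estimated correlation. MYH7 rose by 4.78 ± 0.866 and 4.52 ± 0.855 (atrial and ventricular). For the 14 calcium handling and ion channel genes, 7 rose and 0 fell in the atrial course, and 8 rose and 0 fell in the ventricular course, with adjusted p = 0.00119 and 0.00920 for the list and adjusted p = 0.278 and 0.288 with an estimated correlation. Calsequestrin CASQ2 rose by 3.34 and 3.01, and with atrial day 20 in place of day 45 it stood at -0.10 and was not called. Its ventricular call was lost from day 12 (1.26) and with log2(TPM + 1) (0.83). Among the 20 fatty acid oxidation and oxidative metabolism genes, 8 rose and 0 fell in the atrial course, and 4 rose and 1 fell in the ventricular course, with adjusted p = 0.00119 and 0.0236 for the list and adjusted p = 0.278 and 0.363 with an estimated correlation. The fatty acid transporter CD36 rose by 3.09 and 4.71, the atrial call being lost with day 20 as the late day (1.19). Among the 14 cell cycle genes, 0 rose and 8 fell in the atrial course, with an adjusted p = 0.00119 for the list and an adjusted p = 0.413 with an estimated correlation. Among the 10 endothelium markers, 5 rose and 3 fell in the atrial course, and 1 rose and 8 fell in the ventricular course, with adjusted p = 0.164 and 0.000742 for the list and adjusted p = 0.622 and 0.259 with an estimated correlation. In the ventricular course CDH5 (-4.09) and PECAM1 (-4.02) fell, while PECAM1 rose by 5.34 in the atrial course, where it was not called with day 20 as the late day (1.35). Among the 10 epicardium markers, 5 rose and 1 fell (7 and 1 adjusted over the list alone) in the ventricular course, with an adjusted p = 0.0236 for the list and an adjusted p = 0.288 with an estimated correlation. Among the 11 ventricular markers, 6 rose and 3 fell in the atrial course, and 7 rose and 1 fell in the ventricular course, with adjusted p = 0.164 and 0.00443 for the list and adjusted p = 0.622 and 0.288 with an estimated correlation. IRX4 (3.95) and FHL2 (3.80) rose in the atrial course. Of 6 neural markers tested, 3 rose and 1 fell in the ventricular course, with an adjusted p = 0.340 for the list and an adjusted p = 0.434 with an estimated correlation. The neuronal gene STMN2 rose by 7.16. The matrix genes OGN and MGP went from 0.0244 ± 0.0227 and 0.0224 ± 0.0388 CPM to 146 ± 58.8 and 39.6 ± 14.3, among the largest atrial rises, and the largest ventricular rises included the chemokine CCL21 (8.34) and the sulfotransferase SULT1E1 (7.65, not called up to day 15, 0.95). Called genes numbered 2056 higher and 1495 lower in the atrial and 2116 and 1701 in the ventricular course (467 and 2755 with log2(TPM + 1), 896 and 5030 with log2(TPM + 0.1)). Mitochondrial ribosomal RNA took 38.0% of counts on ventricular day 10 and 55.3% on day 30, and counts outside structural RNA averaged 18690000 and 13850000 (24600000 and 19720000 on atrial days 11 and 45). Without structural RNA and histone genes the ventricular step had 2018 genes higher and 1762 lower.

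The second question was how atrial and ventricular libraries differed at matched stages, with the library sets differing as described above. The nuclear receptors NR2F1 and NR2F2, factors of atrial identity, were higher in the atrial libraries from day 4 on, and HAND1 and HEY2, factors of the ventricular and left heart programme, were lower at the stages given here. NR2F1 was higher by 6.76 ± 0.586 on day 4, 9.26 ± 0.704 on day 6, 7.89 ± 0.501 on day 11 against days 10 and 12 and 7.0 ± 0.682 on the last days. It held 14, 14 and 15 counts over the 3 libraries of ventricular days 6, 10 and 30 and overlaps NR2F1-AS1 on the opposite strand, so that these values are uncertain. NR2F2 was higher by 4.26 ± 0.451, 3.45 ± 0.421, 2.82 ± 0.321 and 3.04 ± 0.414 at the same stages. HAND1 was -3.45 on day 2, -5.00 on day 4, -4.60 on day 6 and -3.48 on the last days. Its direct value in early cardiomyocytes is not given here. HEY2 was -2.21 on day 6, -3.36 in early cardiomyocytes and -3.41 on the last days. Relative to day 2, NR2F2 was higher in the atrial course by 4.67 ± 1.02 on day 4 and 3.45 ± 0.987 on the last days (adjusted p = 0.00184 and 0.0113). HAND1 was -1.56 ± 0.657 on day 4, 2.04 ± 0.60 in early cardiomyocytes and -0.03 ± 0.718 on the last days relative to day 2 (adjusted p = 0.107, 0.0155 and 1.00), so that its differences on day 4 and the last days were not shown to differ from that of day 2. In early cardiomyocytes the change of HAND1 was called and more upward in the atrial course, against the direction of its direct differences. HEY2 was -2.32 ± 0.470 and -2.37 ± 0.483 in early cardiomyocytes and on the last days (adjusted p = 0.000697 and 0.000632).

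On day 2, the HOX genes HOXA2 (-6.27) and HOXB3 (-5.91) were lower in the atrial libraries. Of 20 retinoic acid response genes tested, 1 was higher and 12 lower, with an adjusted p = 0.0239 for the list and an adjusted p = 0.959 with an estimated correlation. Of 11 cohesin and CTCF genes tested, 0 were higher and 6 lower, with an adjusted p = 0.00191 for the list and an adjusted p = 0.959 with an estimated correlation. SMC3 (-1.99) and the cohesin loader NIPBL (-1.45) were lower. Of 17 primitive streak and mesendoderm genes tested, 5 were higher and 0 lower, with an adjusted p = 0.625 for the list and an adjusted p = 0.959 with an estimated correlation. Among the 12 cardiac mesoderm genes, 0 were higher and 6 lower, with an adjusted p = 0.264 for the list and an adjusted p = 0.959 with an estimated correlation. The largest differences lay in structural RNAs and histone genes, with SCARNA2 (8.33), a small Cajal body RNA, and HIST1H4K (8.82) higher, and the mitochondrial ribosomal RNAs RNR2 (-9.16) and RNR1 (-9.04) lower. HIST1H4K belongs to a family of near-identical copies and its value is uncertain. In all, 3772 genes were higher and 3099 lower (1555 and 2290 with log2(TPM + 1), 2716 and 3581 with log2(TPM + 0.1)).

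On day 4, WNT2 stood at 7.56 ± 2.45 CPM in the atrial and 0.00956 ± 0.0166 in the ventricular libraries, OSR1 was higher by 4.66 ± 0.587, while the retinoic acid synthesis enzyme ALDH1A2 was lower (-4.66 ± 1.12, or -2.81 without ventricular day 4 replicate 2). Among the 10 posterior second heart field genes, 9 were higher and 1 lower, with an adjusted p = 0.000571 for the list and an adjusted p = 0.213 with an estimated correlation. Among the 20 retinoic acid response genes, 11 were higher and 0 lower, with an adjusted p = 0.00152 for the list and an adjusted p = 0.497 with an estimated correlation. The retinal reductase DHRS3 (5.82) and HOXA3 (5.20) were higher. For the 12 cardiac mesoderm genes, 0 were higher and 11 lower, with an adjusted p = 0.000571 for the list and an adjusted p = 0.213 with an estimated correlation. MESP2 (-4.92) and LGR5 (-4.31) were lower. Among the 17 primitive streak and mesendoderm genes, 0 were higher and 12 lower, with an adjusted p = 0.00680 for the list and an adjusted p = 0.213 with an estimated correlation. Among the 22 sarcomere genes, 1 was higher and 10 lower, with an adjusted p = 0.0214 for the list and an adjusted p = 0.873 with an estimated correlation. TNNI1 (-4.18), MYL4 (-4.13) and the actin ACTC1 (-3.92) were lower. Of 10 endoderm markers tested, 8 were higher and 1 lower (9 and 1 adjusted over the list alone), with an adjusted p = 0.0941 for the list and an adjusted p = 0.873 with an estimated correlation. TTR (7.28) and AFP (6.63) were higher, AFP without a call under log2(TPM + 1) (2.29). The phosphatase DUSP9 (8.64) was among the largest differences. In all, 3343 genes were higher and 3448 lower (1270 and 2905 with log2(TPM + 1), 2047 and 4749 with log2(TPM + 0.1)). Relative to day 2 it was 803 and 1263 (423 and 727 in both).

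On day 6, WNT2 (6.23), the forkhead factor FOXF1 (4.90) and the WNT antagonist SFRP5 (4.46) were higher in the atrial libraries. For the 10 posterior second heart field genes, 8 were higher and 0 lower, with an adjusted p = 0.000554 for the list and an adjusted p = 0.434 with an estimated correlation. For the 20 retinoic acid response genes, 12 were higher and 1 lower (13 and 1 adjusted over the list alone), with an adjusted p = 0.00330 for the list and an adjusted p = 0.729 with an estimated correlation. HOXA3 (6.61) and the retinoic acid hydroxylase CYP26B1 (4.70) were higher. For the 22 sarcomere genes, 1 was higher and 15 lower, with an adjusted p = 0.00330 for the list and an adjusted p = 0.861 with an estimated correlation. MYOZ2 (-3.86), the troponin TNNC1 (-3.31) and ACTN2 (-3.19) were lower. Of 12 cardiac mesoderm genes tested, 0 were higher and 8 lower, with an adjusted p = 0.00994 for the list and an adjusted p = 0.729 with an estimated correlation. Among the 10 anterior second heart field genes, 1 was higher and 5 lower, with an adjusted p = 0.293 for the list and an adjusted p = 0.861 with an estimated correlation. TBX1 (4.12) was higher and FGF8 (-3.59) lower. Among the 12 fibroblast and extracellular matrix markers, 1 was higher and 6 lower, with an adjusted p = 0.180 for the list and an adjusted p = 0.861 with an estimated correlation. For the 10 endothelium markers, 0 were higher and 6 lower (0 and 7 adjusted over the list alone), with an adjusted p = 0.290 for the list and an adjusted p = 0.861 with an estimated correlation. In all, 3483 genes were higher and 3657 lower (1467 and 2622 with log2(TPM + 1), 2466 and 4331 with log2(TPM + 0.1)), and relative to day 2 the numbers were 704 and 1167.

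In early cardiomyocytes, atrial day 11 was set against ventricular days 10 and 12, and the connexin GJA5 (4.27) and the potassium channel KCNA5 (3.33) were higher in the atrial libraries. Among the 16 atrial markers, 8 were higher and 1 lower, with an adjusted p = 0.0392 for the list and an adjusted p = 0.726 with an estimated correlation. For the 11 ventricular markers, 3 were higher and 4 lower, with an adjusted p = 0.871 for the list and an adjusted p = 0.981 with an estimated correlation. IRX4 (-4.27 ± 0.828) was lower and MYL3 (1.83 ± 0.327) higher. Of 10 posterior second heart field genes tested, 9 were higher and 0 lower, with an adjusted p = 0.0142 for the list and an adjusted p = 0.726 with an estimated correlation. Of 10 endothelium markers tested, 0 were higher and 8 lower, with an adjusted p = 0.0547 for the list and an adjusted p = 0.981 with an estimated correlation. PECAM1 (-5.05) and CDH5 (-3.36) were lower. Among the 10 endoderm markers, 0 were higher and 5 lower, with an adjusted p = 0.285 for the list and an adjusted p = 0.981 with an estimated correlation. APOA2 (-5.63) and TTR (-4.62) were lower. Among the 11 cohesin and CTCF genes, 0 were higher and 3 lower, with an adjusted p = 0.0392 for the list and an adjusted p = 0.981 with an estimated correlation. In all, 3561 genes were higher and 3425 lower (1396 and 2200 with log2(TPM + 1), 2346 and 3912 with log2(TPM + 0.1)). Relative to day 2 it was 992 and 1356 (438 and 757 in both).

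The last days set atrial day 45 against ventricular day 30, so that the days differ as well as the courses. The natriuretic peptide NPPA (4.42 ± 0.728) and the potassium channel KCNJ3 (3.49 ± 0.543) were higher in the atrial libraries, while MYL4 (0.66) was not called, though it was without ventricular day 30 replicate 1 (1.12) and with log2(TPM + 1) (1.03). For the 16 atrial markers, 9 were higher and 1 lower, with an adjusted p = 0.0525 for the list and an adjusted p = 0.816 with an estimated correlation. Of 11 ventricular markers tested, 0 were higher and 5 lower, with an adjusted p = 0.337 for the list and an adjusted p = 0.849 with an estimated correlation. Among the 10 sinoatrial and pacemaker genes, 6 were higher and 2 lower, with an adjusted p = 0.387 for the list and an adjusted p = 0.816 with an estimated correlation. The homeobox factor SHOX2 (3.25), TBX3 (2.09) and HCN4 (1.81) were higher, and SHOX2 lost its call without atrial day 45 replicate 3 (1.25) and with only the compared groups fitted (3.30). Of 14 glycolysis genes tested, 6 were higher and 0 lower, with an adjusted p = 0.0176 for the list and an adjusted p = 0.816 with an estimated correlation. PFKL (2.62) and ENO1 (2.43) were higher. For the 11 cohesin and CTCF genes, 1 was higher and 6 lower, with an adjusted p = 0.0176 for the list and an adjusted p = 0.816 with an estimated correlation. For the 10 endoderm markers, 0 were higher and 8 lower, with an adjusted p = 0.205 for the list and an adjusted p = 0.816 with an estimated correlation. AFP (-9.67) and APOA2 (-7.66) were lower. For the 10 epicardium markers, 0 were higher and 5 lower, with an adjusted p = 0.255 for the list and an adjusted p = 0.816 with an estimated correlation. TCF21 (-3.26) and BNC1 (-2.84) were lower. Among the 10 endothelium markers, 7 were higher and 2 lower, with an adjusted p = 0.302 for the list and an adjusted p = 0.816 with an estimated correlation. PECAM1 (4.08) was higher and TEK (-3.84) lower. With atrial day 20 against ventricular day 30 the value was 1.01 for TCF21, -1.26 for MYL4 and 0.09 for PECAM1, with TCF21 and PECAM1 not called. With atrial day 20 against ventricular day 15 it was 0.80, -2.13 and -1.83, and AFP (-1.83), ENO1 (0.88) and TBX3 (0.91) lost their call. Elastin, ELN (9.35), was among the largest differences toward the atrial libraries. In all, 4018 genes were higher and 3682 lower (3265 and 982 with log2(TPM + 1), 4992 and 2075 with log2(TPM + 0.1)). Relative to day 2 it was 1369 and 1389 (789 and 831 in both).

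**Figure D3:**
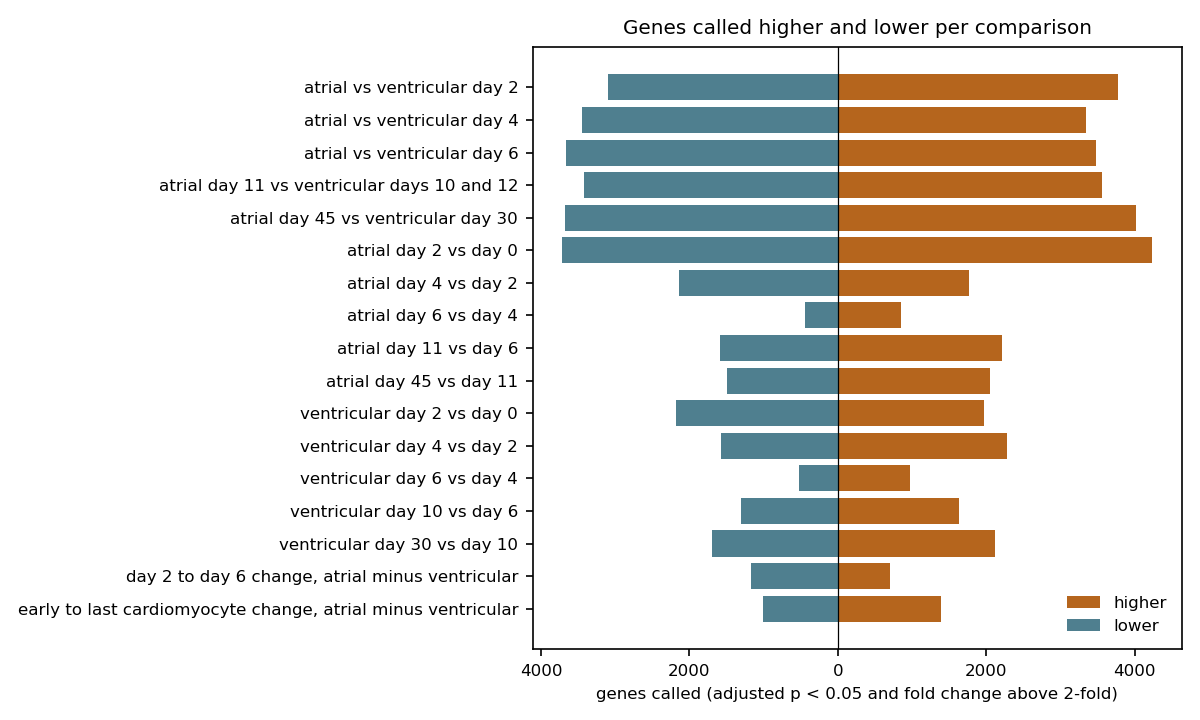
Genes called higher (bars to the right) and lower (bars to the left) in each of the 17 comparisons, in numbers of genes. The atrial day 2 against day 0 comparison had the most calls (4239 higher, 3712 lower) and atrial day 6 against day 4 had 851 higher and 449 lower.

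The third question was whether the courses changed differently over time, which the difference of their changes tests with any constant offset between library sets removed. From day 2 to day 6, HOXA3 (11.02 ± 1.18), whose exons overlap HOXA-AS2 and HOXA-AS3 on the opposite strand so that its value is uncertain, changed more upward in the atrial course. Of 20 retinoic acid response genes tested, 15 changed more upward and 1 more downward (17 and 1 adjusted over the list alone) in the atrial course, with an adjusted p = 5e-19 for the list and an adjusted p = 0.00154 with an estimated correlation. Most of these 20 genes were lower in the atrial libraries on day 2, and the difference of changes holds that day 2 difference too. The HOXA3 difference on day 6 alone, given above, was smaller. Among the 10 posterior second heart field genes, 6 changed more upward and 0 more downward (7 and 0 adjusted over the list alone) in the atrial course, with an adjusted p = 1.27e-13 for the list and an adjusted p = 0.00154 with an estimated correlation. OSR1 (8.56) and FOXF1 (6.57) were among them. Of 22 sarcomere genes tested, 0 changed more upward and 6 more downward in the atrial course, with an adjusted p = 7.92e-05 for the list and an adjusted p = 0.403 with an estimated correlation. TNNC1 (-3.77) and ACTN2 (-3.06) changed more downward in the atrial course. For the 17 primitive streak and mesendoderm genes, 2 changed more upward and 6 more downward (2 and 9 adjusted over the list alone) in the atrial course, with an adjusted p = 0.00472 for the list and an adjusted p = 0.20 with an estimated correlation. EVX1 (-6.77) and FGF8 (-5.26) changed more downward and CDX2 (6.33) more upward. The cystatin CST1 (-9.43) was among the largest downward differences. In all, 704 genes changed more upward and 1167 more downward in the atrial course.

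From early to last cardiomyocytes, the endothelial genes PECAM1 (9.13 ± 0.984), CDH5 (6.42 ± 0.910) and ESAM (5.50 ± 0.790) changed more upward in the atrial course. For the 10 endothelium markers, 7 changed more upward and 1 more downward (7 and 2 adjusted over the list alone) in the atrial course, with an adjusted p = 6.69e-06 for the list and an adjusted p = 0.309 with an estimated correlation. Among the 14 glycolysis genes, 4 changed more upward and 0 more downward (6 and 0 adjusted over the list alone) in the atrial course, with an adjusted p = 1.07e-06 for the list and an adjusted p = 0.583 with an estimated correlation. SLC2A3 (1.83) and ENO1 (1.69) were among them. Among the 6 neural markers, 1 changed more upward and 2 more downward in the atrial course, with an adjusted p = 0.271 for the list and an adjusted p = 0.739 with an estimated correlation. PAX6 (-3.35) and DCX (-3.29) changed more downward, but were not called with log2(TPM + 1) (-0.54 and -0.13), nor DCX with log2(TPM + 0.1) (-0.92). In all, 1393 genes changed more upward and 1003 more downward in the atrial course (2095 and 208 with log2(TPM + 1), 3909 and 420 with log2(TPM + 0.1)), or 2040 and 2251 with no fold threshold, so that the balance of directions depended on the setting.

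The same step was then compared between the courses across all 19992 genes, with genes not independent of each other. Pearson's r of the log2 fold changes was 0.550 for day 4 against day 2 (Spearman's rho 0.494), 0.386 for day 6 against day 4 (0.304), 0.455 for day 6 to early cardiomyocytes (0.471) and 0.433 for early to last cardiomyocytes (0.385). Genes called higher in both courses numbered 886, 388, 845 and 968 in these steps, where independent lists would share 202, 41.5, 181 and 218. Genes called lower in both numbered 955, 150, 561 and 586, against 169, 11.8, 104 and 127. Genes called in opposite directions numbered 116, 33, 77 and 147.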

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

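The test of GC content and length was written before its result was seen, and the counts of other splits and all other tests of the 3 patterns below were chosen after the result was seen.

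The changes below differed between the courses in edgeR's test of the difference itself, atrial minus ventricular, and each is a difference of log2 fold changes with an SE between 0.249 and 1.20 and an adjusted p of at most 0.0379. From day 2 to day 6 the atrial change was more upward for HOXA3 (11.02), OSR1 (8.56), FOXF1 (6.57), CDX2 (6.33) and the growth factor IGF2 (2.90). It was more downward for ACTN2 (-3.06), TNNC1 (-3.77), the metallothionein MT1X (-4.46), FGF8 (-5.26), EVX1 (-6.77) and CST1 (-9.43). From day 2 to day 4 it was more upward for OSR1 (8.99), HOXB2 (7.40), TBX5 (6.22), NR2F2 (4.67), HAND2 (4.41) and RARB (4.02). It was more downward for DKK1 (-1.93), TBXT (-2.74), FGF4 (-2.88) and TNNI1 (-2.90). From early to last cardiomyocytes it was more upward for PECAM1 (9.13), CDH5 (6.42), ESAM (5.50), FHL2 (1.95), SLC2A3 (1.83) and ENO1 (1.69), and more downward for DCX (-3.29) and PAX6 (-3.35). TBX5, HAND2 and RARB held 8.62, 4 and 13 counts over the atrial day 2 libraries and FGF4 held 4 over those of atrial day 4. EVX1 and MT1X held 7 and 13.1 counts over the atrial day 6 libraries, so that the sizes of these differences are uncertain. Leaving out each library in turn moved sizes too, with CDX2 between 5.79 and 8.52 and HOXA3 between 10.04 and 12.55. Of the 29 differences, 25 kept their call without each library of their groups in turn. HAND2 lost it without ventricular day 2 replicate 1 (3.75). DKK1 lost it without atrial day 2 replicate 1 (-1.65), replicate 1 or 2 of atrial day 4 (-1.77 and -1.86) or ventricular day 4 replicate 1 (-1.69). FGF4 lost it without atrial day 2 replicate 3 (-2.78), replicate 1 or 3 of atrial day 4 (-2.79 and -2.71) or any of ventricular day 4 replicates 1, 2 and 3 (-2.92, -2.73 and -3.0). TNNI1 lost it without any of atrial day 2 replicates 1, 2 and 3 (-2.94, -3.11 and -2.63), atrial day 4 replicate 3 (-2.77), ventricular day 2 replicate 2 (-2.64) or ventricular day 4 replicate 2 (-1.97).

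In the first pattern, many genes differed between atrial and ventricular libraries on every day compared (6871 on day 2 and 7140 on day 6). For the 1871 genes called in the difference of the changes from day 2 to day 6, an offset that is the same on every day is argued against, and GC content and length as the whole cause are argued against for 3001 of 5664 day 2 calls (53.0%) that passed in the same direction after both trends were removed. The other 47.0% lost their call as the median size of the log2 fold change of these 5664 genes went from 1.64 (SD 2.44) to 1.06 (SD 2.09), and they stay open, as the day 2 log2 fold change followed GC content across genes (Spearman's rho 0.53, and -0.07 for length, with 84.5% of tested genes covered). Preparation or read counting that differed between the library sets is a candidate explanation. Day 0, of neither course, sided with the ventricular libraries in mitochondrial ribosomal RNA (33.2% of counts) and small structural RNA (0.015%). Shares of non-whole estimates, genes overlapping an opposite-strand exon minus genes with none, were 21.3 points at day 0 (19.8 to 22.5). They were 21.4 in ventricular and -2.56 in atrial libraries (-3.59 to -0.99). On day 6, 6074 genes were called and not the same way relative to day 2. For these, a stable course difference and an offset between library sets cannot be told apart, as each course has its own library set. The biological difference between the courses stays open and untested.

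In the second pattern, day 0 replicate 3 held 366 counts of MYH6 against 59 and 62 in replicates 1 and 2, 46 of MYH7 against 1 and 4, and 289 of TNNT2 against 156 and 106, and the treatment label of this replicate names the atrial differentiation beside its day 0 title. Reads from an atrial library are argued against, since at the lower 95% limit of the ratio set by the MYH6 excess each of 12 atrial libraries of day 6 or later left at least 3 of 20 abundant genes short of their expected count, and would bring at least 105 counts of H19, the most abundant of the 20 in each, of which replicate 3 had 0 (upper 95% limit 3.69). Reads from a ventricular library stay open as a candidate explanation, with 0 of the 20 genes short for 2 of 15 ventricular libraries, which would bring 2.34 and 1.86 counts of H19, under that limit, where the other 13 would bring 3.72 to 99.7. This test replaced earlier ones on the same counts after their values were seen, its limits cover counting error only, and its ratio rests on MYH6 alone. No biological explanation was tested, and the counts of this library were kept.

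In the third pattern, replicate 2 stood apart from replicates 1 and 3 in the ventricular course, with TBX5 at 59.8 CPM on day 6 against 11.6 and 22.5, and at 97.0 CPM on day 12 against 53.0 and 57.2, but on day 2 it was the lowest of the 3 in TBX5 (0.113 CPM against 0.341 and 0.836) and TNNT2 (0.169 against 0.580 and 0.341). Wells of replicate 2 that ran ahead of replicates 1 and 3 are a candidate explanation, as its deviation from the group mean correlated across genes with the next step of the atrial course on 5 of 5 days from 2 to 12 (r from 0.126 to 0.299) and was the highest of the 3 on each, while replicates 1 and 3 lay between -0.252 and 0.047. With independent days, chance would let any 1 number lead on all 5 days in 1.23% of cases, and genes are not independent. The pattern was found after all 9 groups of these days and several other steps had been looked at, and in the atrial course the values lay between -0.097 and 0.109. Nothing in the labels ties the number 2 to a shared plate or day, and a batch or culture difference between the wells stays untested.

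Other splits of the same libraries were counted in fits of those libraries alone. For atrial day 11 against ventricular days 10 and 12, 1 of 84 splits, the real one, gave as many genes (6862, highest other 1), a share under 0.05 if the wells are independent. Every other split mixes the 2 library sets. The count therefore shows that these sets of libraries differ and cannot tell the course from the library set. The other comparisons of a pair of groups have 10 splits each, too few for a share under 0.05. Their real counts were 6684, 6554, 7103 and 7122 for atrial against ventricular days 2, 4, 6 and the last days, 8027, 4267, 1943, 4182 and 3644 for the atrial steps in order of time, and 3813, 2558, 588, 2295 and 2835 for the ventricular steps. The highest other split gave 1 for ventricular day 10 against day 6 and 0 for each of the rest. For the difference of the changes from day 2 to day 6, 4 of 100 splits gave as many as the real one (1864), and for early to last cardiomyocytes 4 of 100 (1857). The highest other splits gave 4629 and 7819 genes, several times the real count, which points to a structure of the samples. The first exchanged the course of 6 of 6 day 2 libraries and 2 of 6 day 6 libraries, and the second of 2 of 9 early and 6 of 6 last libraries, so that the difference between the library sets entered the difference of changes. Splits that exchange the course are therefore no clean reference for an unchanged difference, and whether chance can be excluded stays open for both.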

How the results depend on the processing

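Values relative to day 2 and those without genes overlapping an opposite-strand exon were chosen after the data were seen. All other alternatives were planned.

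Counts of called genes are given in 1 order: atrial against ventricular on day 2, day 4, day 6, in early cardiomyocytes and on the last days, then the 5 atrial steps and the 5 ventricular steps from day 0 on, then the differences of the early and of the late change. They were 6871, 6791, 7140, 6986, 7700, 7951, 3903, 1300, 3811, 3551, 4151, 3862, 1501, 2934, 3817, 1871 and 2396. All 17 counts stayed within 1.5 times under DESeq2, RLE scaling, no filter and the removal of structural RNA and histone genes. RLE scaling moved the share of higher calls by at most 4.53 percentage points and the median of all genes by -0.0929 to 0.0459 (log2). The TPM scalings moved that share by over 10 percentage points in most comparisons, with the numbers given beside each. Of 190 named values, 185 were called, 166 of them kept call and direction under every alternative run for them and 19 lost the call under at least 1, while 4 values that were not called became so under at least 1. Values relative to day 2 were not among these alternatives. HAND1 on day 4 and the last days kept its call here but was not called relative to day 2. For 44 of the named values, 35 of the 166 among them, the removal of structural RNA, histone and opposite-strand genes gives no value, since it takes the gene out.

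With no fold threshold, which passes smaller changes, the first 15 counts were 11574, 11566, 11938, 12567, 12337, 12472, 7231, 2172, 8044, 7118, 8512, 7838, 2519, 6602 and 8053 and the last 4291. With limma on log2(TPM + 1), where the pseudocount shrinks the fold changes of low genes, the first 16 without the last ventricular step were 3845, 4175, 4089, 3596, 4247, 4838, 1666, 461, 1768, 1414, 1978, 1725, 724, 1428 and 1106. With log2(TPM + 0.1) the last ventricular step had 5926 and the difference of the late change 4329. With only the compared groups in the fit, ventricular day 4 against day 2 had 2472 and day 6 against day 4 580, while atrial day 4 against day 2, day 6 against day 4 and day 11 against day 6 had 4227, 1947 and 4154. The full fit pools unequal spreads (mean SD of log2 CPM per gene 0.42 on ventricular and 0.18 on atrial day 4). Without structural RNA, histone and opposite-strand genes and those not in the annotation, which tests fewer genes, the first 6 were 4051, 4005, 4252, 4210, 4602 and 4856. Relative to day 2, the day 4, day 6, early and last counts were 2066, 1871, 2348 and 2758. With atrial day 20 as the late day the last atrial step had 2320 calls, and the last ventricular step had 2440 from day 12 and 1970 up to day 15, over fewer days. Over the first 15 comparisons, 140 list tests by camera had an adjusted p below 0.05, against 36 with an estimated correlation. The correlation of the courses' steps was 0.619, 0.523, 0.544 and 0.521 over genes called in at least 1 of the steps, against 0.550, 0.386, 0.455 and 0.433 over all genes, and 0.455 with RLE for day 6 to early cardiomyocytes. The cause of these shifts was not tested further.

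The direction turned for 4 named values, all with other days compared. CASQ2 stood at -0.10 with atrial day 20 as the late day against 3.34. Against ventricular days 30 and 15, atrial day 20 gave -1.26 and -2.13 for MYL4, 1.01 and 0.80 for TCF21 and, for day 15, -1.83 for PECAM1, where the last days gave 0.66, -3.26 and 4.08.

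Each of 120 counts with 1 library left out stayed within 1.5 times, at 71.8 to 117.4% of the full count. In the order above they ranged over 6552 to 6798, 6288 to 7277, 6804 to 7098, 6670 to 7047, 7235 to 7614, 7547 to 7980, 3533 to 3668, 967 to 1056, 3327 to 3638, 3231 to 3305, 3804 to 4126, 3318 to 3958, 1077 to 1762, 2562 to 3011, 3389 to 3939, 1564 to 1921 and 1845 to 2547. The correlations of the steps ranged over 0.514 to 0.556, 0.331 to 0.414, 0.420 to 0.453 and 0.402 to 0.447.

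The labels tie no replicate number across groups and not every same-numbered pair correlated above 0.1, so the numbers were not treated as pairs. Deviations from the group means correlated by 0.028 on average (lowest -0.187), against -0.014 for different numbers, and within a library set by 0.066 against -0.033. With their own number 30 of 42 libraries correlated best, a hint from the data, not the design, that same-numbered libraries may be related. With the replicate number as a block (replicate block), the counts were 100.1 to 103.6% of those without it, for instance 6882 on day 2 and 2453 for the difference of the late change. The block gives a number the same effect in both courses, so it does not test a pairing within 1 course. Depth limits what can be called at low levels, as a gene at 0 in a group of 3 libraries is bounded only by the floor of 3 counts.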

Other observations

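The genes in this part were chosen after their values were seen, while their comparisons were planned.

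The imprinted growth genes H19, a maternally expressed non-coding RNA, and IGF2, the paternally expressed insulin-like growth factor beside it, reached different levels in the courses. H19 had 0 counts in all 3 day 0 libraries. In the atrial course H19 stood at 1.95 ± 0.20 CPM on day 2, 2932 ± 107 on day 4, 5848 ± 450 on day 6 and 7796 ± 1624 on day 45. In the ventricular course it stood at 44.0 ± 65.2 CPM on day 4, 67.9 ± 63.5 on day 6 and 312 ± 122 on day 30. H19 was higher in the atrial libraries on day 6 (6.43 ± 1.07, adjusted p = 1.1e-05) and on the last days (4.64 ± 0.980, adjusted p = 0.000205) by edgeR's quasi-likelihood test, where the library sets also differ. IGF2 stood at 1.83 ± 1.01 CPM at day 0 and, on day 2, at 2.85 ± 0.609 in the atrial and 1.90 ± 0.147 in the ventricular course, a difference that was not called (0.58 ± 0.576, adjusted p = 0.402). On day 6 IGF2 reached 2796 ± 243 and 250 ± 174 CPM, and its rise from day 2 was larger in the atrial course (2.90 ± 0.763, adjusted p = 0.00952). That difference of rises cancels a constant offset between the library sets, but IGF2 overlaps an exon of IGF2-AS on the opposite strand, so that its values are uncertain. H19 had 0 counts on ventricular day 2, so its difference of rises has no reliable value. The parental origin of these transcripts cannot be read from counts per gene.

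SLC30A1, a zinc exporter induced by zinc, stood at 20.8 ± 1.49 CPM at day 0, 68.3 ± 35.3 on ventricular day 2 and 18.7 ± 4.38 on ventricular day 6, against 18.1 ± 1.30 and 1.69 ± 0.239 on atrial days 2 and 6. Its rise from day 0 to ventricular day 2, within 1 library set, was 1.72 ± 0.350 (adjusted p = 0.000176), and it was lower in the atrial libraries on day 6 (-3.47 ± 0.398, adjusted p = 7.52e-09), where the library sets also differ. The metallothionein MT2A, which binds zinc and copper, rose by 4.89 ± 0.797 in that ventricular step (adjusted p = 1.1e-05) and stood at 9.82 ± 5.25 CPM on ventricular and 0.0255 ± 0.0257 on atrial day 6. MT1X stood at 22.2 ± 8.05 CPM on atrial and 122 ± 69.4 on ventricular day 2, and its change from day 2 to day 6 was more downward in the atrial course (-4.46 ± 1.15, adjusted p = 0.00843). Metallothionein genes are near-identical copies that share reads, so MT2A and MT1X values are uncertain. The cause was not tested.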
